A study of Mus musculus with 6 samples.

How the data were processed

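Gene expression was measured by RNA sequencing in 6 libraries of group 2 innate lymphoid cells (ILC2s) from the lungs of C57BL/6 mice aged 8 weeks. Per the labels' protocols, 3000 cells were sorted for each library, cDNA was made with the SMART-Seq v4 kit, and 1 ng of cDNA entered the Nextera XT kit, which does not mark strand. The libraries form 2 groups of 3: Control (both Il7 alleles flanked by loxP sites) and Il7cKO (the same alleles with Cre under the surfactant protein C promoter). The gate in the labels lists as negative the T cell markers CD3, CD4, CD8 and CD5, the B cell markers CD19 and B220, the myeloid markers CD11b, CD11c and Gr-1, the high-affinity IgE receptor, the red cell marker Ter119 and the leukocyte marker CD45, and lists no positive marker. The labels do not say whether the libraries come from separate mice, so every p-value measures the spread between these samples.

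The deposited values are a signal made by the authors from read counts, each count divided by 1 scaling factor per library. Every column of the deposited table is a whole multiple of its smallest value above 0, so whole reads were recovered by division: 100% of values above 0 lay within 0.01 of a whole read. Median-of-ratios factors computed from the deposited values were 1 after rounding in all 6 libraries, so the table already carries that scaling. Per the submitters' processing notes, Trimmomatic 0.33, HISAT2 2.1.0, featureCounts and Subread 1.6.5 were used with the mm10 build. Those notes give neither the annotation release nor a strand setting. Where genes overlap, on either strand, reads from the shared stretch therefore cannot be told apart. Overlap was judged on whole gene spans, introns included, so an overlap named below need not involve counted reads. Reads shared with pseudogenes or other near-identical copies make ribosomal protein genes, mitochondrially encoded genes and Actb uncertain.

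The table holds 46078 Ensembl gene IDs, of which 45143 matched GENCODE mouse release 21 (M21, on GRCm38, the same assembly as mm10), the source of symbols, coordinates, GC content and transcript lengths. A read was present for 27672 genes. Recovered reads came to 2158249, 4335414 and 3883411 in Control 1, 2 and 3 and to 1617100, 1238318 and 2986388 in Il7cKO 1, 2 and 3. A count of 0 allows up to 3 reads, which is a value of 3.27, 1.6 and 1.89 in the Control libraries and of 4.66, 5.84 and 2.48 in the Il7cKO libraries. Such floors and the exact 95% intervals of ratios cover counting error only, because reads without molecular identifiers are not independent molecules.

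Values are called normalised read counts from here on. The 10298 genes with a mean of at least 10 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (a linear model with a variance trend) on log2(value + 1), two-sided, with genotype group as the only term. Benjamini-Hochberg adjustment ran over the tested genes, with a threshold of 0.05. Log2 fold changes are Il7cKO minus Control, with the fitted standard error (SE).

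For ILC2 biology, IL-7 signalling, survival, growth, metabolism, migration, activation, RNA quality and markers of other cell types, 35 gene lists were fixed. The 32 lists with at least 4 tested members were tested with camera, limma's competitive set test, at a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with the correlation estimated per list and fry, a rotation test of whether a list's genes move one way on balance. For each list the text gives the median log2 fold change and the members past the threshold when adjusted over all tested genes and when adjusted over the list alone. Shares of a library's summed values were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

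The lists, the tests and the rule for the genes named were set before the data were examined. The rule takes Il7, Il7r, Gata3, Il1rl1, Il5, Il13, Areg, Sftpc and Ptprc. It adds, per direction, the 10 genes with the largest fold change among those that passed with no overlap between groups, and, where fewer than 10 passed, the non-overlapping genes with the smallest unadjusted p. Predicted genes without a proper name are passed over. It also adds up to 4 tested members of each list with the smallest unadjusted p. Actb, the genes of the gate, and other genes said to be singled out were chosen after their values were seen.

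Alternatives were other pseudocounts, filters, scalings, variance models and thresholds, library weights, replicate number as a block, leaving out each library in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. After the data had been seen, 3 more were added: removing each library's trend on GC content and transcript length (natural splines with 5 degrees of freedom), thinning all libraries to the depth of the shallowest, and comparing Il7cKO 3 alone with the 3 controls. The last assumes that the lone library varies as the controls do. A list test there would rest on genes as replicates, so for lists only its medians are read. Ranges of camera adjusted p over all alternatives include it.

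The fit was tested on simulated counts for the 10298 genes at the depths and spread of the real libraries, with 200 genes changed. For Il7cKO against Control, limma recovered 24% of genes raised 2-fold, 90% raised 4-fold, 98% raised 16-fold and 68% lowered 4-fold, and called 4 unchanged genes. In 20 simulations of unchanged data, camera called a list in 1. Each gene was drawn independently there, whereas estimated correlations within the real lists reached 0.80 (mitochondrially encoded genes). The simulations therefore do not show how often camera calls lists whose members vary together.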

Results

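Lung ILC2s, tissue-resident lymphocytes that respond to epithelial alarmins and secrete type 2 cytokines, were profiled by RNA sequencing in 6 libraries. The 3 Control libraries came from mice with loxP-flanked Il7 alleles, and the 3 Il7cKO libraries from mice that also carried Cre under the promoter of surfactant protein C, a product of alveolar type II epithelial cells. Depth was 3459025 ± 1148952 reads in Control and 1947269 ± 919617 in Il7cKO (mean ± SD, n = 3 each; exact permutation p = 0.2), and the deepest library held 3.50 times the reads of the shallowest. The comparison asks what differs in the ILC2 transcriptome when alveolar epithelial cells lack IL-7, a cytokine that supports lymphocyte survival through the IL-7 receptor and STAT5. Il7 had 6, 4 and 3 reads in Control 1 to 3 and 2, 3 and 1 in Il7cKO 1 to 3, and Sftpc had 1, 2 and 19 against 1, 9 and 9. Neither gene reached the level needed for a test. Cre acts in the epithelium, so the Il7 level in sorted lymphoid cells does not check the genotype labels.

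By limma, 26 of 10298 genes rose in Il7cKO libraries and 0 fell, with 1496 genes at an unadjusted p under 0.05 (812 higher, 684 lower). On the same genes edgeR gave 61 higher and 0 lower genes on the recovered reads, and DESeq2 gave 248 and 33. Inmt, an amine methyltransferase abundant in lung fibroblasts, had a mean normalised read count of 3.51 ± 4.09 in Control and 149 ± 34.6 in Il7cKO (SD, n = 3 each). Col3a1, a fibrillar collagen chain, went from 6.03 ± 4.80 to 232 ± 118, and Gsn, the actin-severing protein gelsolin, from 139 ± 57.1 to 2504 ± 1355. Log2 fold changes of the 26 genes ran from 1.6 to 5.54, and 6 of the 26 belong to the lists of fibroblast and endothelial markers fixed beforehand.

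The 10 genes with the largest fold changes lie on 6 autosomes of mm10. On chromosome 1 these were Cavin2 (51289126 to 51302960), a caveolar coat protein, at log2 5.50 ± 0.68 (SE), Col3a1 (45311538 to 45349706) at 5.19 ± 0.65, and Prelp (133910304 to 133921414), a matrix proteoglycan, at 4.56 ± 0.75. On chromosome 2 were Serping1 (84765387 to 84775444), the C1 inhibitor, at 5.34 ± 0.73, and Itga8 (12106632 to 12301922), an integrin of mesenchymal cells, at 4.86 ± 0.69. Cyp4b1 (115624725 to 115647723), a lung cytochrome P450, and Nfib (82290173 to 82705750), a transcription factor, both on chromosome 4, stood at 5.01 ± 0.77 and 4.45 ± 0.65. Inmt (chromosome 6, 55170626 to 55175043) stood at 5.54 ± 0.70, Tcf21 (chromosome 10, 22817281 to 22820174), a transcription factor of lung fibroblasts, at 4.82 ± 0.77, and Cldn5 (chromosome 16, 18776847 to 18778262), the tight junction claudin of endothelium, at 5.05 ± 0.80. Their limma adjusted p-values ran from 0.0194 for Inmt, Cavin2 and Col3a1 to 0.0439 for Cldn5, Tcf21 and Prelp. Over the 3 controls Cavin2, Cldn5 and Tcf21 had 1, 3 and 2 reads. The ratio of their pooled reads per depth, Il7cKO to Control, was 222 (exact 95% interval 39.0 to 8826), 64.0 (21.3 to 316) and 74.8 (20.1 to 628). At so few control reads the fitted log2 fold change depends on the pseudocount of 1, which these ratios do not use. Over the alternatives it ran from 2.62 to 8.08 for Cavin2, 2.44 to 7.41 for Cldn5 and 2.17 to 7.25 for Tcf21, which the SE does not cover. Annotated genes overlap the spans of Cavin2, Col3a1, Itga8, Tcf21, Prelp and Nfib, and reads from a shared stretch, if any were counted, cannot be separated.

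**Figure D1:**
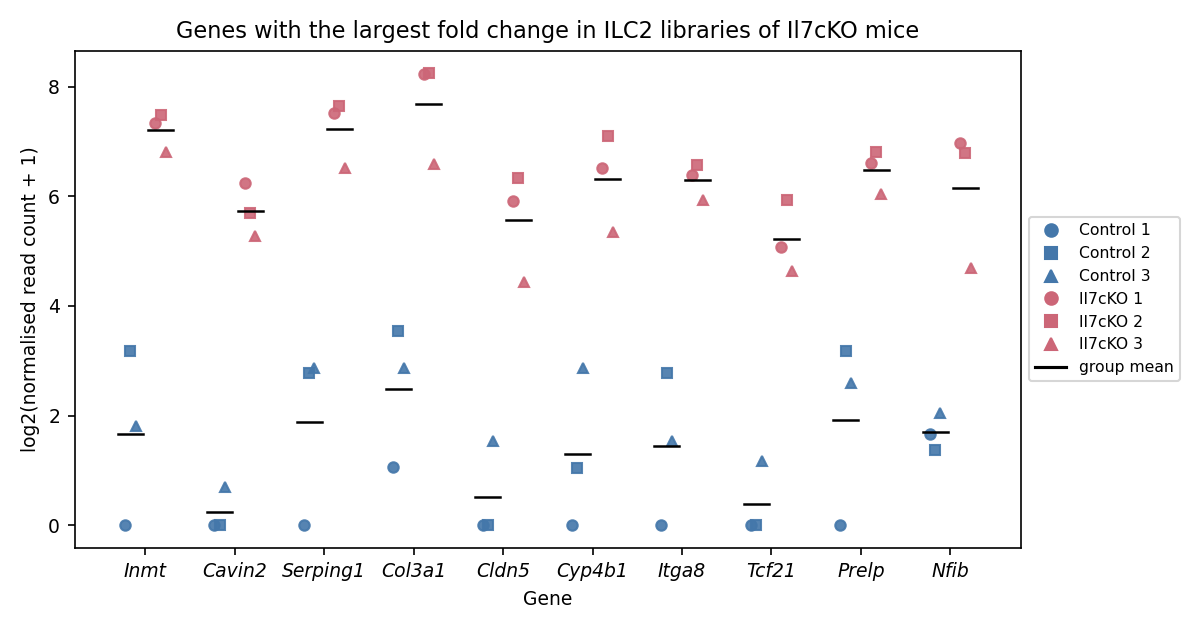
Log2(normalised read count + 1) of the 10 genes with the largest fold change among those that passed, in each library (blue Control, pink Il7cKO; circle, square and triangle for replicates 1, 2 and 3; black bar for the group mean). Each gene is higher in all 3 Il7cKO libraries than in all 3 controls, and Il7cKO 3 is the lowest of the Il7cKO libraries for all 10.

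All 26 genes were higher in every Il7cKO library than in every control. Groups that did not overlap, in either direction, were shown by 17.8% of tested genes (1838), against 10% by chance. By limma, leaving out Control 1, 2 or 3 gave 14, 20 and 143 higher and 0, 0 and 5 lower genes, with 828 and 807 genes at an unadjusted p under 0.05 in the first 2, leaving out Il7cKO 1 or Il7cKO 2 gave 0 (885 and 1082 at an unadjusted p under 0.05), and leaving out Il7cKO 3 gave 516 higher and 534 lower. In Il7cKO 3 alone against the controls no gene passed limma, with 517 at an unadjusted p under 0.05, and the 26 genes had a median log2 difference of 3.24.

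As lists, the fibroblast, muscle and mesothelial markers and the endothelial markers both rose, with a camera adjusted p of 7.6e-17 for the first and 7.9e-13 for the second. With an estimated correlation the camera adjusted p was 0.411 for both lists and by fry 0.0668 for both, and over all alternatives it ran from 1.2e-25 to 0.411 and from 6.0e-24 to 0.411. Of 28 fibroblast markers 14 were tested, and 13 of these were higher, with a median log2 fold change of 4.02. Of the 14, 5 passed over all genes and 12 when adjusted over the list alone. Besides Gsn, Col3a1 and Inmt, Col1a2, a chain of type I collagen, went from 3.39 ± 0.31 to 86.8 ± 49.4. The member that was not higher was Npnt, a basement membrane protein, at 586 ± 104 in Control and 460 ± 132 in Il7cKO. All 16 tested endothelial markers were higher, with a median of 3.21; 1 passed over all genes and 13 when adjusted over the list alone. With a mean of at least 100, only Calcrl and Pecam1 were left, fewer than the 4 tested members a list needed. Their median was 0.32 and the call was lost, which says little of the other endothelial markers. Plvap, a diaphragm protein of fenestrated vessels, stood at 13.0 ± 17.8 against 155 ± 84.4, and the receptor tyrosine kinases Kdr and Tek at 1.5 ± 0.56 and 2.33 ± 2.04 against 36.7 ± 31.6 and 39.9 ± 20.8. In Il7cKO 3 alone the medians were 3.32 and 2.58. These markers were thus higher in the same 3 libraries for every gene group that follows, and within those libraries Il7cKO 1 and 2 differed from Il7cKO 3.

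ILC2 identity genes as a list did not pass (24 tested, 7 higher and 17 lower, median -0.22, camera adjusted p = 0.0729), and none passed over all genes. Gata3, the transcription factor that defines ILC2s, stood at 6176 ± 1374 in Control and 10465 ± 2665 in Il7cKO (log2 0.75 ± 0.26 SE, limma adjusted p = 0.244), with 3 overlapping genes. Il1rl1, the IL-33 receptor, stood at 4127 ± 329 against 2416 ± 1076 (-0.86 ± 0.29, limma adjusted p = 0.235), and in Il7cKO 3 it was 3626, close to the 3749 of Control 3. Hlf, a transcription factor, stood at 831 ± 150 against 473 ± 263. Adjusted over the list alone, 1 member fell: Ly6a (Sca-1), from 808 ± 377 to 269 ± 63.0. Ptprc, which encodes CD45, was abundant in all libraries although the gate lists CD45 as negative, at 3336 ± 276 against 2579 ± 1025 (-0.44 ± 0.26, limma adjusted p = 0.478). The log2 difference of Ptprc was 0.18 in Il7cKO 3 alone. The fibroblast and endothelial markers were higher in the same Il7cKO libraries, and the median of the identity list in Il7cKO 3 alone was -0.02. The identity list passed as lower without Control 1 (-0.22), without Il7cKO 3 (-0.33), with no filter (-0.22) and with GC content and length trends removed (-0.26). Without Il7cKO 3, Gata3 passed as higher (0.95) and Il1rl1 (-1.20) and Ptprc (-0.74) as lower. Il1rl1 also passed with library weights (-1.03), which gave Il7cKO 3 the least weight.

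Type 2 effector genes fell as a list, with 18 of 23 lower and a median of -0.35 (camera adjusted p = 0.0154). With an estimated correlation the camera adjusted p was 0.632, by fry 0.438, and over all alternatives it ran from 0.00268 to 0.710. No member passed over all genes, and 1 fell when adjusted over the list alone: Cxcl3, a neutrophil chemokine, from 344 ± 17.8 to 113 ± 75.7. Its relative Cxcl2 stood at 5183 ± 162 against 2823 ± 1487, and Il6 went the other way, at 25.8 ± 20.5 against 63.5 ± 22.9. The classical ILC2 cytokines did not pass limma: Il13 stood at 41.6 ± 15.9 against 13.7 ± 12.4 (log2 -1.86 ± 0.67 SE, adjusted p = 0.261) and Il5 at 4803 ± 1463 against 3147 ± 133 (-0.57 ± 0.24, adjusted p = 0.313), lower in all 3 Il7cKO libraries and with 1 overlapping gene. Areg, an epidermal growth factor receptor ligand of tissue repair, stood at 5132 ± 1039 against 4848 ± 868 (-0.08 ± 0.23, limma adjusted p = 0.898). The list median was -0.11 without Il7cKO 1 (camera adjusted p = 0.196), which ends the call, -0.62 without Il7cKO 3, and 0.06 in Il7cKO 3 alone, which turns the direction.

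Receptors for alarmins, neuropeptides and lipids did not pass (25 tested, 10 higher, 15 lower, median -0.14, camera adjusted p = 0.144, 0 when adjusted over the list alone). Cysltr2, a cysteinyl leukotriene receptor, stood at 120 ± 24.7 against 60.3 ± 8.44, Crlf2, a chain of the TSLP receptor, at 121 ± 20.1 against 63.3 ± 27.9, and Ptger4, a prostaglandin E2 receptor, at 478 ± 105 against 284 ± 104. The list passed with no filter (-0.15). The median was 0.01 in Il7cKO 3 alone, and the stromal markers were higher in the same Il7cKO libraries.

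With all 6 libraries the IL-7 axis did not pass. Only without Il7cKO 3 did Il7r (log2 -0.61) and the list of IL-7 and STAT5 components (median -0.27) pass as lower. This was 1 of 22 alternatives for Il7r and 1 of 20 with camera at its preset correlation for the list. Without Il7cKO 3, 516 genes passed as higher and 534 as lower, so passing there is not particular to the IL-7 axis. Il7r, the IL-7 receptor alpha chain, stood at 2623 ± 104 against 2388 ± 1153 (log2 -0.24 ± 0.29 SE, limma adjusted p = 0.747), and by library at 1813 and 1637 in Il7cKO 1 and 2 but 3716 in Il7cKO 3, above all controls. Of 22 tested genes for IL-7, other common gamma chain receptors and STAT5 signalling 16 were lower (median -0.18, camera adjusted p = 0.101, 0 when adjusted over the list alone). Among these the IL-2 receptor chains Il2ra and Il2rb stood at 1792 ± 181 and 2083 ± 419 against 1104 ± 618 and 1195 ± 684, whereas the kinase Akt1 stood at 237 ± 292 against 886 ± 529. Genes induced by STAT5 had a median of -0.03 and a mean of 0.01, with the direction of the test down (27 tested, 13 higher, 14 lower, camera adjusted p = 0.802, 0 when adjusted over the list alone). Cish, a feedback inhibitor of cytokine signalling, stood at 1087 ± 138 against 682 ± 229, Dusp5 at 2097 ± 402 against 1094 ± 828, and the kinase Pim1 at 437 ± 155 against 2323 ± 1611. FOXO1, KLF2 and quiescence genes had a median of 0.04 (27 tested, 14 higher, 13 lower, camera adjusted p = 0.645, 0 when adjusted over the list alone), which turned negative under TMM and quantile scaling, with Cdkn1b, a cell cycle inhibitor, at 64.4 ± 20.4 against 182 ± 117. These 3 lists had medians of -0.02, 0.02 and 0.28 in Il7cKO 3 alone, beside the higher stromal markers of all 3 Il7cKO libraries.

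Survival genes did not pass in either direction. Antiapoptotic genes had a median of 0.10 (14 tested, 10 higher, camera adjusted p = 0.949) and proapoptotic genes of -0.12 (21 tested, 8 higher, camera adjusted p = 0.646), with 0 past the threshold in both when adjusted over the list alone. Gadd45b, a stress-induced survival gene, stood at 5376 ± 218 against 3676 ± 687. Bcl2l11, which encodes the proapoptotic BIM, stood at 424 ± 82.2 against 261 ± 125, and Tnfrsf10b, a death receptor for TRAIL, at 65.5 ± 18.0 against 117 ± 20.2.

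Ribosomal protein genes (median -0.75, camera adjusted p = 2.4e-24) and mitochondrially encoded genes (median -1.09, camera adjusted p = 2.0e-07) fell as lists. With an estimated correlation the camera adjusted p-values were 0.553 and 0.595, by fry 0.154 and 0.313, and over all alternatives they ran from 5.0e-30 to 0.553 and from 5.6e-13 to 0.595. Of 76 tested ribosomal protein genes 72 were lower, 0 passed over all genes, and adjusted over the list alone 43 fell and 1 rose. Rpl32 went from 1011 ± 97.3 to 556 ± 160 and Rps26 from 179 ± 41.0 to 79.2 ± 34.7. All 10 tested mitochondrially encoded genes were lower, 9 of them past the threshold when adjusted over the list alone and 0 over all genes. mt-Cytb, a subunit of respiratory complex III, went from 3576 ± 907 to 1748 ± 693, and mt-Nd1, of complex I, from 2426 ± 455 to 1325 ± 355. The medians were -0.37 and -0.40 in Il7cKO 3 alone, and the fibroblast and endothelial markers were higher in the same Il7cKO libraries.

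Nuclear genes of the respiratory chain, glycolysis and hypoxia genes, and genes of mTORC1 signalling and amino acid uptake fell as lists, with medians of -0.20, -0.24 and -0.24 and camera adjusted p-values of 0.0262, 0.0262 and 0.0154. With an estimated correlation the camera adjusted p was 0.650, 0.411 and 0.430 for these 3 lists, and by fry 0.438, 0.0668 and 0.111. Over the alternatives the lowest camera adjusted p was 0.00787 for glycolysis and 0.00137 for mTORC1 genes. For all 3 lists the highest were those with an estimated correlation. None of their members passed over all genes or when adjusted over the list alone. The respiratory chain list had 36 of 50 lower, with Atp5b of ATP synthase at 2514 ± 161 against 1713 ± 405. The glycolysis list had 19 of 26 lower, with Hif1a, the hypoxia-inducible transcription factor, at 1533 ± 129 against 796 ± 407. The mTORC1 list had 17 of 20 lower, with the kinase Mtor at 118 ± 20.6 against 54.6 ± 16.7 and the leucine transporter subunit Slc7a5 at 120 ± 9.0 against 74.3 ± 11.6. The respiratory chain call was lost without Control 1 (median -0.13), Il7cKO 1 (-0.14) or Il7cKO 3 (-0.15), and the glycolysis call without Control 3 (-0.26). The mTORC1 median was -0.38 without Control 3 and -0.06 in Il7cKO 3 alone, where the other lists had -0.25 and -0.21. Lipid uptake and storage genes did not pass (31 tested, 19 higher, median 0.11, camera adjusted p = 0.923, 0 when adjusted over the list alone). Its members went both ways, with Cd36, a fatty acid scavenger receptor also found on capillary endothelium, at 45.1 ± 50.3 against 176 ± 51.9, and Cpt1a, of mitochondrial fatty acid import, at 240 ± 18.1 against 139 ± 26.2.

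**Figure D2:**
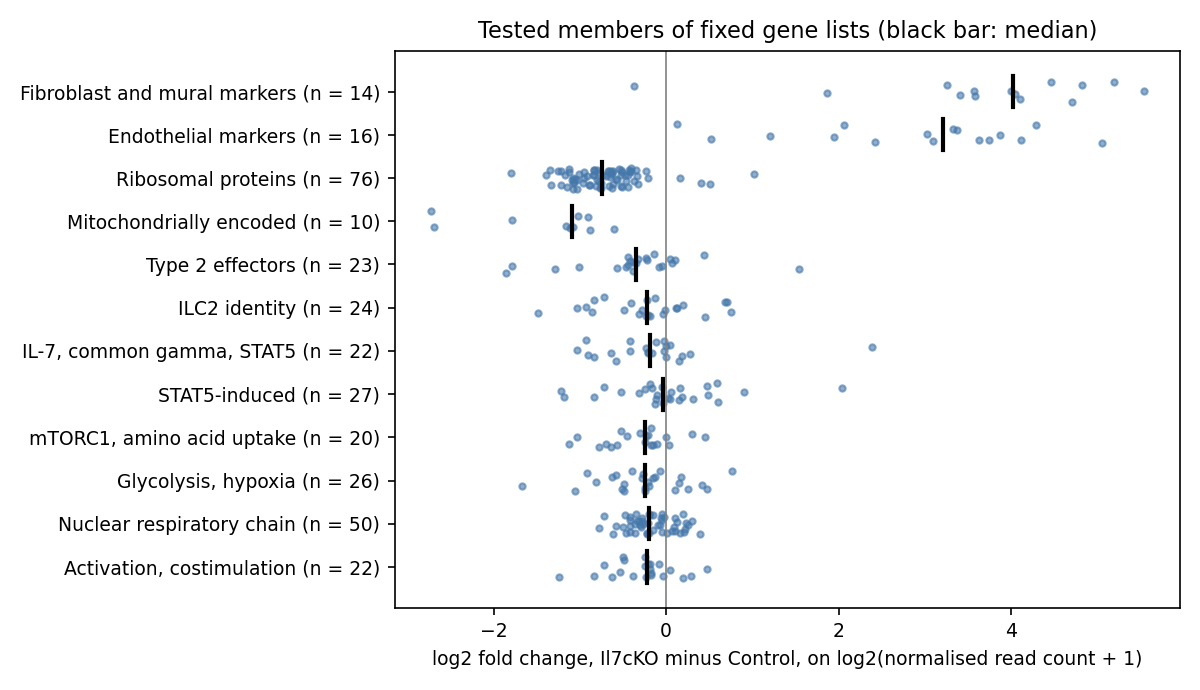
Log2 fold change (Il7cKO minus Control, on log2(normalised read count + 1)) of each tested member of 12 fixed gene lists, with the median as a black bar. Fibroblast and endothelial markers have medians of 4.02 and 3.21, ribosomal protein and mitochondrially encoded genes -0.75 and -1.09, and the other lists shown lie between -0.35 and -0.03.

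Activation and costimulation genes fell as a list, with 18 of 22 lower and a median of -0.22 (camera adjusted p = 0.0262). With an estimated correlation the camera adjusted p was 0.632, by fry 0.438, and over all alternatives it ran from 0.00137 to 0.693. Irf4, a transcription factor of activated lymphocytes, fell when adjusted over the list alone, from 324 ± 37.0 to 144 ± 56.5, and none passed over all genes. Cd28 stood at 117 ± 37.3 against 73.7 ± 15.5. The call was lost without Control 3 (median -0.15) or Il7cKO 1 (-0.10), and the median was -0.37 without Control 2, -0.35 without Il7cKO 2, -0.38 without Il7cKO 3 and 0.02 in Il7cKO 3 alone.

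With all 6 libraries the other activation, stress and migration lists did not pass. Interferon-stimulated genes had a median of -0.37 (27 tested, 19 lower, camera adjusted p = 0.0529), with Ly6a past the threshold when adjusted over the list alone and Oas3 at 70.6 ± 33.4 against 20.8 ± 17.4. This list passed as lower without Control 2 (-0.29), Control 3 (-0.37) or Il7cKO 2 (-0.26), after thinning (-0.33) and without a variance trend. Its median in Il7cKO 3 alone was -0.33. NF-kB targets had a median of -0.02 (24 tested, 11 higher, camera adjusted p = 0.629), and inhibitory and exhaustion genes of -0.16 (17 tested, 13 lower, camera adjusted p = 0.122), both with 0 past the threshold when adjusted over the list alone. Ctla4, an inhibitory receptor, stood at 234 ± 113 against 101 ± 48.8, and the inhibitory list passed as lower without Control 2 (-0.27). Immediate early and dissociation stress genes had a median of 0.11 (35 tested, 20 higher, camera adjusted p = 0.339), and adjusted over the list alone 2 rose: Egr1, from 620 ± 191 to 1476 ± 235, and Ccn1, a secreted matrix protein, from 17.6 ± 29.6 to 165 ± 88.0. Unfolded protein response genes had a median of -0.16 (25 tested, 18 lower, camera adjusted p = 0.144, 0 when adjusted over the list alone), with Herpud1 at 193 ± 36.5 against 429 ± 132 and the chaperone Hyou1 at 125 ± 47.2 against 39.6 ± 33.7, and this list passed as lower without Control 3 (-0.31). Chemokine receptors and adhesion molecules had a median of -0.18 (30 tested, 21 lower, camera adjusted p = 0.0729, 0 when adjusted over the list alone), with the integrin Itgal at 1741 ± 236 against 971 ± 391 and S1pr1, the receptor for tissue egress, at 37.2 ± 13.4 against 73.3 ± 22.7. The adhesion list passed as lower without Control 2 (-0.30), without Il7cKO 3 (-0.35) and with no filter (-0.22). Cell cycle genes had a median of 0.35 (40 tested, 27 higher, camera adjusted p = 0.0754, 0 when adjusted over the list alone). The cell cycle list passed as higher without Il7cKO 1 (0.72), without Il7cKO 3 (0.80) and with no filter (0.37). Its median was -0.27 without Il7cKO 2 and -0.20 in Il7cKO 3 alone. Nuclear-retained RNAs had a median of -0.14 (7 tested, 6 lower, camera adjusted p = 0.159), with 1 fallen when adjusted over the list alone: Gm42418, which overlaps ribosomal RNA sequence, from 420 ± 64.4 to 210 ± 101. That list passed as lower without Control 2 (-0.30), and its median in Il7cKO 3 alone was -0.36.

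With all 6 libraries, markers of the other cell types did not pass as lists. In Il7cKO 3 alone T cell and macrophage markers had medians of -0.17 and -0.69. Over all 6 libraries the medians were -0.24 for ILC1 and NK cells (4 tested, camera adjusted p = 0.364), -0.18 for T cells (12 tested, adjusted p = 0.320), 0.07 for macrophages, dendritic cells and monocytes (11 tested, adjusted p = 0.339), negative under quantile scaling, 0.22 for neutrophils (4 tested, adjusted p = 0.923) and -0.32 for epithelium (5 tested, adjusted p = 0.199). For ILC3s the median was -0.06 but the mean 0.05 and the direction of the test up (7 tested, camera adjusted p = 0.821). For mast cells, basophils and eosinophils the median was -0.31 but the mean 0.40 and the direction of the test up (5 tested, camera adjusted p = 0.949). Adjusted over the list alone, Cd3e, a chain of the T cell receptor complex, fell from 19.2 ± 7.44 to 1.38 ± 2.38, while Apoe, an apolipoprotein, rose from 13.1 ± 12 to 106 ± 56.0, and Gata2 from 2.25 ± 3.02 to 23.1 ± 6.46; the ILC1, ILC3, neutrophil and epithelial lists had 0. With too few tested members for a set test, Ighm stood at 377 ± 20.7 against 599 ± 175 among 2 B cell genes, Hba-a1 fell from 26.1 ± 22.3 to 3.47 ± 1.74 when adjusted over 2 red cell genes alone, and Xist was the 1 tested sex-linked gene. Among genes for the gate, Cd4, Cd8a and Ly6g had at most 1 read in any library, Cd3g had 121 to 536 reads, and Cd19 had 20 reads in Control 3 and 0 in the others.

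No gene passed as lower by limma, where the smallest adjusted p among lower genes was 0.0960, and the following did not pass but lay lower in all 3 Il7cKO libraries. AA467197, a small protein of the mitochondrial respiratory chain, stood at 58.2 ± 9.24 against 16.1 ± 4.64 (log2 -1.82 ± 0.36 SE), and Cxcl3, already given among type 2 effectors, at -1.78 ± 0.37. The actin-severing protein Cfl1 (cofilin) stood at 4436 ± 507 against 2241 ± 590 and Cap1 at 232 ± 98.7 against 38.0 ± 44.4. The transcription factors Epas1 and Sp1 stood at 513 ± 58.9 and 78.3 ± 16.4 against 219 ± 74.7 and 26.4 ± 10.1. Xist, the RNA of the inactive X chromosome, stood at 359 ± 144 against 132 ± 36.3, Fam168a at 129 ± 14.3 against 54.4 ± 16.1 and Ogfr at 138 ± 17.4 against 56.2 ± 21.3. Ly6a, given among identity genes, completes the 10. Beside Xist, the Y chromosome genes Ddx3y and Uty had at most 1 read in any library, which gives no sign of male cells. All 10 passed as lower without Il7cKO 3, with no filter and with library weights, where 534, 97 and 96 genes passed as lower. With DESeq2, where 33 genes passed as lower, 9 of the 10 passed (not Cap1). Xist and Ly6a also passed without Control 3. Library weights gave Il7cKO 3 the least weight (0.427), so that setting is not independent of leaving it out. Annotated genes overlap AA467197, Epas1, Fam168a, Cap1, Cfl1 and Xist.

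Libraries within Il7cKO stood apart from one another. On the first principal component (51.4% of variance) Il7cKO 1 and 2 lay at 57.8 and 56.6, Il7cKO 3 at -7.27, and the controls at -49.2, -41.3 and -16.6. Actb, which was singled out after its values were seen, had 51147 and 52798 normalised reads in Il7cKO 1 and 2 against 1818 in Il7cKO 3 and 3275 ± 388 in Control. Mitochondrially encoded genes took 0.484 ± 0.119% of a Control library and 0.236 ± 0.091% of an Il7cKO library (n = 3 each; exact permutation p = 0.1, the smallest possible), and ribosomal protein genes 1.41 ± 0.20% and 0.929 ± 0.153% (exact permutation p = 0.1). Fibroblast markers took 0.0336 ± 0.0079% and 0.167 ± 0.070%, and endothelial markers 0.0282 ± 0.0059% and 0.0607 ± 0.0166% (exact permutation p = 0.1 for both). The 10 genes with the most reads took 5.94 ± 0.50% and 7.83 ± 1.46% (exact permutation p = 0.2), and haemoglobin genes 0.00226 ± 0.00282% and 0.000141 ± 0.000072% (exact permutation p = 0.1), where Control 3 held 0.00551% and Control 1 and 2 held 0.000695% and 0.000577%.

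**Figure D3:**
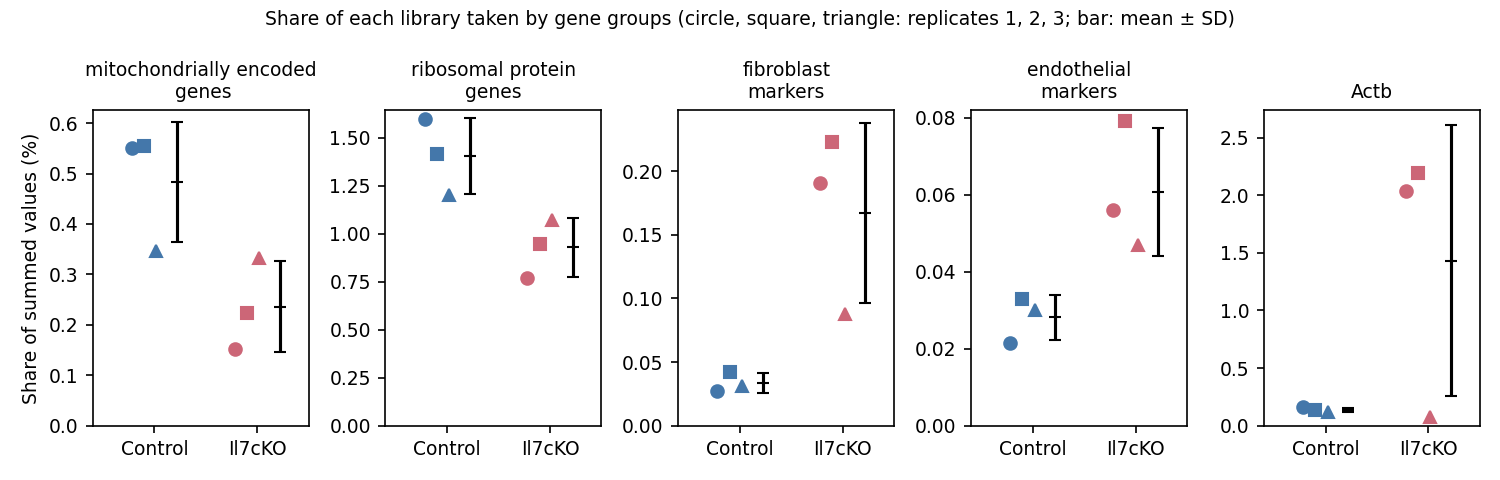
Share of each library's summed normalised reads, in percent, taken by mitochondrially encoded genes, ribosomal protein genes, fibroblast markers, endothelial markers and Actb (blue Control, pink Il7cKO; circle, square and triangle for replicates 1, 2 and 3; bar for mean ± SD). Il7cKO 1 and 2 hold 2.04% and 2.19% of their reads in Actb, and Il7cKO 3 holds 0.0737%.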

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

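Removing GC content and length trends, thinning to equal depth and leaving out Il7cKO 1 and 2 together were chosen after the data had been seen; the other alternatives were fixed before. The 26 higher genes kept their direction under every alternative in which they were tested, but the number past the threshold varied and the cause was not tested unless stated. Higher genes numbered 7 with a pseudocount of 0.1 and 47 with 10, 308 with no filter (97 lower) and 0 with a mean of at least 100, where limma tested 4 of the 26 and 755 genes had an unadjusted p under 0.05. They numbered 15 with TMM, 43 with quantile scaling, 41 without a variance trend, 199 with library weights (96 lower), 61 with edgeR, 248 with DESeq2 (33 lower), 59 at an adjusted p under 0.1 (1 lower), 13 with GC content and length trends removed and 0 without Il7cKO 1 and 2. With replicate number as a block (the replicate block) 13 were higher, 11 of them among the 26. Deviations of same-numbered libraries correlated at -0.10, -0.14 and -0.16, and no library correlated best with its own number. These values gave no sign that the numbers pair the libraries, but so few libraries cannot exclude it. Median-of-ratios rescaling changed no count because its factors are 1 after rounding, and requiring an absolute log2 fold change of 1 removed no gene. Leaving out each library in turn gave 0 to 516 higher and 0 to 534 lower genes.

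The 9 list calls (fibroblast 4.02, endothelial 3.21, ribosomal protein -0.75, mitochondrially encoded -1.09, type 2 -0.35, mTORC1 -0.24, glycolysis -0.24, respiratory chain -0.20, activation -0.22) number 0 by camera with an estimated correlation and 0 by fry, where 5 lists had an unadjusted p under 0.05. These tests leave the medians as they are and change only the p. With a mean of at least 100, where fewer genes are tested, 4 lists passed. Endothelial markers (0.32, on Calcrl and Pecam1 alone), mTORC1 (-0.17), glycolysis (-0.24), respiratory chain (-0.093) and activation (-0.19) did not. Cell cycle (-0.086) and T cell (0.057) medians changed sign there. With library weights glycolysis (-0.25), respiratory chain (-0.15) and activation (-0.24) did not pass, and Areg changed sign (0.0016). Without Il7cKO 1 and 2, the medians were 0.063 for type 2, 0.017 for activation and -0.059 for mTORC1 genes. There the sign also changed for Il7r (0.50), Ptprc (0.18) and the medians of alarmin receptors (0.013), STAT5-induced (0.019), antiapoptotic (-0.069), cell cycle (-0.20), lipid (-0.13), NF-kB (0.11), ILC3 (0.15), macrophage (-0.69), neutrophil (-1.31) and mast cell genes (0.41). FOXO1 (0.28), interferon (-0.33), nuclear-retained RNA (-0.36) and T cell lists (-0.17) kept their direction there. Leaving out 1 library brought calls that all 6 libraries did not give: without Il7cKO 3, Il7r, Gata3, Il1rl1, Ptprc, the 10 named lower genes and the identity, IL-7 component, cell cycle and adhesion lists passed.

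Medians near 0 changed sign elsewhere: FOXO1 genes with a pseudocount of 10 (-0.055), TMM (-0.026), quantile scaling (-0.059) and trends removed (-0.053), and macrophage genes with quantile scaling (-0.0655) and trends removed (-0.044). With no filter the neutrophil median changed from 0.22 to -0.33 and the epithelial median from -0.32 to 0.29. Leaving out each library in turn gave medians from -0.62 to -0.11 for type 2, -0.29 to -0.21 for glycolysis, -0.28 to -0.13 for respiratory chain and -0.38 to -0.10 for activation genes. Ranges that crossed 0 were STAT5-induced -0.095 to 0.050, FOXO1 -0.13 to 0.17, proapoptotic -0.25 to 0.0062, cell cycle -0.27 to 0.80, inhibitory -0.27 to 0.0066, NF-kB -0.13 to 0.037, ILC3 -0.16 to 0.043, macrophage -0.62 to 1.01 and neutrophil -0.48 to 0.59, as well as Areg itself at -0.22 to 0.075. Thinning to equal depth left the median of the stromal markers at 3.61. Il7 and Sftpc, with at most 6 and 19 reads in a library, lay below the minimum for a test. The size of the difference moved with other choices. Over the alternatives the median of fibroblast markers ran from 1.86 (no filter) to 4.47 (without Il7cKO 3). That of endothelial markers ran from 0.32 (mean of at least 100, on Calcrl and Pecam1 alone) to 4.16 (pseudocount of 0.1).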

Other observations

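The tests that compare Il7cKO 3 alone with the controls, and the test of the ILC2 share, were chosen only after the result was seen. The corrections for GC content, transcript length and depth were also added after the data had been seen, before the values they gave.

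Of the 26 higher genes, 14 have not been described so far, and those given here with values were picked after their values were seen. Mmp2, a gelatinase, had a mean normalised read count of 25.7 ± 6.78 in Control and 147 ± 70.3 in Il7cKO, Spon1, a matrix protein, 11.9 ± 5.92 and 113 ± 14, and Adamts2, a procollagen peptidase, 3.27 ± 1.12 and 47.4 ± 24.9 (SD, n = 3 each). Acvrl1, the endothelial BMP receptor ALK1, stood at 3.69 ± 1.80 and 61.8 ± 25, and Pmp22, a membrane protein of myelin and fibroblasts, at 5.89 ± 0.94 and 73.9 ± 19.9. Cebpd, an inflammatory transcription factor, stood at 59.4 ± 11.7 and 241 ± 85.9, Iigp1, an interferon-induced GTPase, at 3.0 ± 0.41 and 40.3 ± 6.13, and Ptov1 at 62.3 ± 16.7 and 187 ± 15.6, and Iigp1 and Ptov1 were highest in Il7cKO 3. The remaining genes, Plpp3, Fhl1, Colec12, Tspan7, Crispld2 and Tmem204, had log2 fold changes from 2.75 (Colec12) to 4.30 (Fhl1).

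The 30 tested fibroblast and endothelial markers had a median log2 fold change of 3.58 (quartiles 2.57 and 4.11), and of these 4 had a control mean of at least 50 and 1 is in another fixed list. After GC content and length trends were removed the median was 3.58, and after thinning to equal depth it was 3.61, which argues against either as the whole cause. A second list of 43 tested genes of these cell types had 42 higher (Fn1 and Ly6c1, whose values had been seen, were dropped before the test, and Epas1, the lower gene, seen after it was listed but before the test, was kept), a median of 2.51 (2.90 for fibroblast and 1.45 for endothelial genes, or 2.60 and 0.88 in Il7cKO 3 alone) and no gene past the threshold over all genes by limma. Its 7 genes with a control mean of at least 50 are all endothelial and had log2 fold changes from -1.28 (Epas1) to 0.96 (Bmpr2), among them Ctla2a (3682 in Control, 3831 in Il7cKO), in Il7cKO the most abundant gene of the lists ahead of Gsn (2504). Testing required a mean of at least 10 over the 6 libraries. Genes low in Control, such as Efemp1 (0.72, 23.6 in Il7cKO), therefore entered only where Il7cKO was high. This filter favours higher genes, here and among the 30 markers of the first lists, so the count of 42 and the median of 2.51 add little support. In genes already high in Control a small addition would show less, so those 7 genes do not decide the endothelial part. The values are compatible with fibroblasts and endothelial cells, or their RNA, in the sorted fraction. Support from the second list is less for endothelial genes (1.45 against 2.90). The gate as listed, with CD45 negative, would not remove such cells, but a sort on CD45-positive cells would. Ptprc was abundant (3336 in Control, 2579 in Il7cKO), at 1925 to 3761 in every library, beside Gata3 at 5348 to 13083. These values argue against a sort of CD45-negative cells alone. How CD45 was used in the sort is not otherwise given, so how such cells or RNA would have entered stays open. Expression by ILC2s themselves and genotype were not tested and stay open.

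Ribosomal protein genes (median -0.75) and mitochondrially encoded genes (-1.09) were lower in Il7cKO. Removing GC content and length trends gave -0.77 and -1.09, which argues against those trends as the whole cause. In Il7cKO 3 alone the medians were -0.37 and -0.40. For the ribosomal protein genes, where alone this was tested, a property of Il7cKO 1 and 2 and a difference of the whole group cannot be told apart, with 1 library left to decide it. Reads shared with pseudogenes or nuclear copies, and genotype, were not tested and stay open.

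Type 2 effector genes were lower in Il7cKO, with a median of -0.35. Removing GC content and length trends gave -0.40, which argues against those trends. The test of a lower share of ILC2s assumed that it would raise markers of every other cell type alike. The lower quartile of fibroblast markers lay 2.61 above the higher of the upper quartiles of macrophage and epithelial markers. Added fibroblasts and endothelial cells, or their RNA, could lower the share without raising the other markers. The test therefore cannot decide, and a lower share stays open. An earlier test, which it replaced, asked how many ILC2 identity genes were higher. There 7 of 24 were, too close to its bound to decide. The median was 0.06 in Il7cKO 3 alone, and without Il7cKO 1 it was -0.11 and did not pass, so the difference may be a property of Il7cKO 1 and 2, though the data it was found from cannot settle it. Genotype stays open, untested apart from these libraries.

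The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For genes past the limma threshold, 1 of the 10 splits, the real one, gave as many as 26, and the highest of the others gave 0. For gene lists past camera, 3 of the 10 gave at least the 9 of the real split, which is among them, and the highest other gave 12.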
